A study of Mus musculus with 9 samples.

How the data were processed

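The deposited data are 9 matrices of raw UMI counts per gene and cell barcode, from 10x Chromium 3' libraries of live-sorted cells of mouse pancreas and pancreatic tumours. Per the labels, each library pooled 2 to 3 pancreata and 5000 to 10000 cells were loaded. Per the submitters' notes, reads were aligned and counted with Cell Ranger 7.0.1 on mm10. The annotation version is not given. The matrices hold called barcodes only, 48827 in all, over 31053 genes. Each group had 1 library. Groups and the 9 comparisons, the gene lists, the markers, the rule for named genes and most alternatives were fixed before the data were examined.

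Barcodes with fewer than 500 UMIs or 200 genes (1789) or more than 20% mitochondrial UMIs (1583) were removed. Doublets were removed at a fixed rate of 0.8% per 1000 barcodes by simulated-doublet score (2622), because the automatic score threshold marked almost no barcode in most libraries and 3.04% at most. This left 42833 cells. Counts were scaled to 10000 per cell and log-transformed. With scanpy 1.11.5, 3000 variable genes, 50 principal components and 15 neighbours gave 60 Leiden clusters at resolution 1.5 (leidenalg 0.10.2). No batch correction was applied, since library and group coincide. Clusters were named by markers of 17 classes. A marker counted when it was at least 2-fold above the other cells and seen in 10% of the cluster's cells, and 7 clusters stayed unnamed.

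UMIs were summed per class and library and divided by the class total to give CPM (counts scaled to a fixed total), with exact Poisson intervals. Folds have the exact conditional binomial 95% interval. A side with 0 UMIs was set to a floor of 3 UMIs per library and the fold is written as at least. For each of 29 gene lists the median log2 fold over members with at least 10 UMIs was given a 95% interval from 2000 Poisson resamples. It was also ranked among 10000 random lists matched on expression. Genes, members and cells are not replicates, so no p-value was computed. Shares of cells have exact Clopper-Pearson intervals and ratios of shares a Katz log interval. T cell subsets were counted after thinning each cell to 1000 UMIs. Gene positions come from the GRCm38 annotation GENCODE vM21.

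Named genes had the largest change by the interval bound nearest to no difference, among genes with at least 50 CPM and 30 UMIs in the higher library, in classes with at least 50 cells in both. There were 5 on each side in epithelial-like cells, 3 in fibroblast-like and macrophage or monocyte-like cells and 2 in T-like and neutrophil-like cells. The comparison of 5 weeks with 1 week and the comparisons of both agents with a single agent used 3 on each side in epithelial-like cells only. Mitochondrial, ribosomal protein, unnamed, haemoglobin, immunoglobulin, sex-linked and dissociation stress genes were left out, as were acinar and endocrine markers outside their class and genes below 10% of their level in another class of the same library. The members with the 2 largest and 2 smallest folds were named for the lists described in full. Cdk8, Cxcl2, Dusp6, Mki67 and Kras were named in any case.

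Several choices were made after cell numbers or values were seen. These were the 30-cell minimum per library for a list median, the minimum of 3 measured members, the cluster naming thresholds, leaving unnamed the clusters with innate lymphoid or eosinophil genes and a presumed doublet cluster, and the rule for results set out for a closer look. Subtraction of free RNA was limited to libraries with at least 1% acinar-like cells, also a later choice, and subtracted sums were rounded to whole UMIs. The calculation was tested on simulated data: of 100 genes given a 2-fold difference, 99.0% had an interval excluding no difference, and 95.4% of intervals of unchanged genes covered it. Unchanged lists fell in the outer 5 percentiles in 3.0% of 200 cases. Alternatives tried were a minimum of 1000 UMIs, a mitochondrial limit of 10%, no doublet removal, resolution 0.8, classing each cell by its marker score, median-ratio scaling, thinning, a list minimum of 50 UMIs, free RNA subtraction and shares of all cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.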

Results

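Single-cell RNA sequencing was done on 9 libraries from mouse pancreas and pancreatic tumours. Each library pooled 2 to 3 pancreata and each group had 1 library, so no replicate spread could be measured and no test between groups was run. Intervals below cover counting error only. Most libraries came from mice with orthotopic tumours of the line PKC-HY19636 (HY): vehicle for 1 week, the mutant KRAS inhibitor MRTX1133 for 1 week, and MRTX1133 for 5 weeks. A further 4 HY libraries had 3 weeks of MRTX1133 with 1 week of isotype antibody, of an antibody to CTLA4 (aCTLA4), of a CDK8 inhibitor (CDK8i), or of both. The other 2 came from KPC689 tumours that the labels call resistant (KPC689R), with vehicle or MRTX1133 for 3 weeks. Totals ran from 14553323 to 173941963 UMIs per library, and 1250 to 9710 cells per library were kept.

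Clusters were named by marker genes, and the classes carry the ending -like. Members of a gene list at least 1.5-fold apart are called higher or lower, and each list's median is placed among 10000 random lists of matched expression. Intervals for single genes are 95% exact bounds of the fold. Where the median of all genes was shifted by more than 0.1 (log2) in a class, the shift is given once and list medians also appear relative to it. The labels give no sex of the mice. Leukocytes of the 3 HY libraries without antibody or CDK8i held 257 to 353 CPM of 4 Y-linked genes and at most 2.49 CPM of Xist. In the HY aCTLA4 library the leukocytes held 0.171 CPM of the Y-linked genes and 534 CPM of Xist, and the other 5 libraries held both.

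The comparison of 1 week of MRTX1133 with 1 week of vehicle in HY tumours asks what differs early under the inhibitor. Genes downstream of ERK were lower in epithelial-like cells, contractile and matrix genes were lower in fibroblast-like cells, and proliferation genes were lower in each of 4 classes. Macrophage or monocyte-like cells made up 74.9% (2234 of 2982 leukocytes) against 54.7% (1902 of 3479), a log2 ratio of 0.45 (0.40 to 0.51). T-like cells were 3.65% (109 of 2982) against 6.44% (224 of 3479), a log2 ratio of -0.82 (-1.14 to -0.49). Neutrophil-like cells were 7.85% (234 of 2982) against 20.5% (714 of 3479), a log2 ratio of -1.39 (-1.59 to -1.19). Acinar-like cells were 35.7% of kept cells with the inhibitor and 1.65% with vehicle.

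The epithelial-like class had different cells in the 2 libraries. With vehicle, 789 of 1380 cells lay in 1 cluster and 383 in another, whereas with the inhibitor 122 of 160 cells lay in the cluster with duct genes such as Pkhd1, which held 13 vehicle cells. These 122 cells had 233 CPM of the Y-linked genes and 1.12 CPM of Xist, close to the leukocytes of the same library, while the 38 other epithelial-like cells had 3.39 CPM and 552.5 CPM. Vehicle epithelial-like cells outside the duct-gene cluster had 5.73 CPM of the Y-linked genes and 392 CPM of Xist. List values without that cluster therefore stand beside the full ones. Acinar enzyme genes, whose transcripts took 18.3% of UMIs in the inhibitor library, also had 14 of 14 measured members higher and 0 lower in the epithelial-like class (median log2 fold 6.65, counting interval 6.55 to 6.73, 6.51 relative to all genes, 6.09 without the duct-gene cluster, percentile 100 of random lists). The median of all genes was shifted by 0.14 in epithelial-like, -0.41 in macrophage or monocyte-like and -0.16 in neutrophil-like cells.

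ERK output genes had 3 of 20 measured members higher and 15 lower (median log2 fold -1.21, counting interval -1.52 to -1.004, -1.35 relative to all genes, -1.49 without the duct-gene cluster, percentile 0 of random lists). Dusp5 (5.84-fold lower, 4.67 to 7.39) and Dusp4 (5.46-fold lower, 3.31 to 9.77) stood lowest in the list. Etv1 (6.14-fold higher, 3.61 to 9.94) and Egr1 (4.70-fold higher, 4.41 to 5.01) stood highest. Dusp6, a phosphatase that ERK signalling induces, was 3.56-fold lower (2.59 to 5.03). Hypoxia and glycolysis genes had 0 of 17 measured members higher and 17 lower (median log2 fold -2.65, counting interval -2.84 to -2.21, -2.79 relative to all genes, -1.75 without the duct-gene cluster, percentile 0 of random lists). Adm (at least 36.6-fold lower) and Hk2 (33.2-fold lower, 21.7 to 53.7) stood lowest in the list. Eno1 (2.29-fold lower, 1.95 to 2.70) and Pfkl (2.48-fold lower, 1.85 to 3.39) stood highest. Mesenchymal state genes had 2 of 17 measured members higher and 13 lower (median log2 fold -2.15, counting interval -2.29 to -1.85, -2.29 relative to all genes, -1.26 without the duct-gene cluster, percentile 0 of random lists). Serpine1 (230.1-fold lower, 89.9 to 845) and Twist1 (17.7-fold lower, 4.90 to 147) stood lowest in the list. Sparc (5.14-fold higher, 4.23 to 6.21) and Tgfbi (1.69-fold higher, 1.02 to 2.64) stood highest. MHC class I genes, which present peptides to CD8 T cells, had 16 of 18 measured members higher and 0 lower (median log2 fold 1.96, counting interval 1.44 to 2.18, 1.82 relative to all genes, 1.06 without the duct-gene cluster, percentile 99.99 of random lists). B2m (1.04-fold higher, 0.898 to 1.19) and Nlrc5 (1.46-fold higher, 0.172 to 5.59) stood lowest in the list. H2-Q4 (37.3-fold higher, 20.6 to 67.8) and Psmb9 (37.0-fold higher, 20.9 to 65.8) stood highest. Dissociation stress genes moved with them, with 15 of 18 measured members higher and 0 lower (median log2 fold 2.08, counting interval 2.01 to 2.15, 1.95 relative to all genes, 0.41 without the duct-gene cluster, percentile 100 of random lists).

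Among single genes of the epithelial-like class, Erbb4 (472-fold higher, 368 to 615), Fmo2 (463-fold higher, 327 to 677), Adamts16 (860.0-fold higher, 283 to 4264), Angpt1 (433-fold higher, 275 to 722) and Apoc1 (360.3-fold higher, 258 to 517) stood highest, in a class made up mostly of duct-gene cells with the inhibitor. The lowest were Serpine1, which encodes a plasminogen activator inhibitor, Unc13c (at least 90.7-fold lower) and Hmga2 (96.5-fold lower, 65.8 to 148). Next were Klhl1 (at least 67.9-fold lower) and Stac (273-fold lower, 49.0 to 10776). Kras was 3.33-fold lower (3.01 to 3.68) and Mki67, a proliferation marker, was 1.79-fold lower (1.18 to 2.86). Without values outside the duct-gene cluster, these folds do not show a change within tumour cells. Proliferation genes had 1 of 25 measured members higher and 18 lower (median log2 fold -1.94, counting interval -2.12 to -1.29, -2.08 relative to all genes, -0.57 without the duct-gene cluster, percentile 0 of random lists), and in T-like cells 1 of 23 measured members higher and 15 lower (median log2 fold -1.01, counting interval -1.46 to -0.61, percentile 0.06 of random lists).

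Myofibroblast genes of fibroblast-like cells had 0 of 15 measured members higher and 14 lower (median log2 fold -2.01, counting interval -2.19 to -1.90, percentile 0 of random lists). Acta2 (29.1-fold lower, 22.8 to 37.9) and Cnn1 (26.7-fold lower, 7.32 to 221) stood lowest in the list. Fap (1.36-fold higher, 1.18 to 1.56) and Thbs2 (1.71-fold lower, 1.52 to 1.93) stood highest. Acta2 and Cnn1 encode contractile proteins. This class also differed in clusters: a cluster led by collagen genes made up 41.1% against 94.7% with vehicle, one led by Cfd and Car3 43.8% against 2.54%. Collagen and matrix genes had 0 of 16 measured members higher and 13 lower (median log2 fold -1.71, counting interval -1.75 to -1.67, percentile 0 of random lists). Lox (11.2-fold lower, 9.95 to 12.7) and Loxl2 (7.41-fold lower, 6.09 to 9.09) stood lowest in the list. Col4a2 (1.06-fold lower, 0.988 to 1.13) and Col4a1 (1.27-fold lower, 1.20 to 1.34) stood highest. Proliferation genes had 0 of 25 measured members higher and 23 lower (median log2 fold -3.73, counting interval -4.09 to -3.19, percentile 0 of random lists). By single gene, Cfd (at least 469-fold higher), Car3 (1361-fold higher, 242 to 53992) and Csmd1 (49.9-fold higher, 31.3 to 83.7) stood highest and Ereg (at least 63.3-fold lower), Top2a (101-fold lower, 39.5 to 372) and Actg2 (at least 42.2-fold lower) lowest.

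The leukocyte classes differed in clusters too. Of macrophage or monocyte-like cells, 65.1% and 27.4% with the inhibitor lay in 2 clusters that held 1.26% and 0.16% of vehicle cells, and 1141 and 475 of 1902 vehicle cells in 2 others. Of neutrophil-like cells, 84.2% against 1.68% with vehicle lay in 1 cluster, and a cluster led by Camp and Ngp held 0.85% against 9.94%. A cluster led by Ikzf2 and Ctla4 held 49.5% against 11.2% of T-like cells. List values were not separated by cluster, so they do not tell a change of cells from a change within cells. Dissociation stress genes had 10 of 18 measured members higher and 1 lower in neutrophil-like (median log2 fold 0.71, counting interval 0.45 to 0.83, 0.88 relative to all genes, percentile 95.7 of random lists) and 10 of 18 measured members higher and 2 lower in T-like cells (median log2 fold 0.82, counting interval 0.50 to 0.94, percentile 100 of random lists). In fibroblast-like and macrophage or monocyte-like cells 15 and 10 of 18 were higher, with medians of 1.21 and 0.66.

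Tumour-associated macrophage genes had 4 of 18 measured members higher and 12 lower (median log2 fold -1.22, counting interval -1.24 to -1.19, -0.80 relative to all genes, percentile 0 of random lists). Marco (105-fold lower, 62.5 to 193) and Lyve1 (20.7-fold lower, 18.8 to 22.8) stood lowest in the list. Apoe (4.18-fold higher, 4.16 to 4.20) and C1qb (2.44-fold higher, 2.41 to 2.47) stood highest. MHC class II genes had 5 of 7 measured members higher and 0 lower (median log2 fold 1.22, counting interval 1.17 to 1.28, 1.64 relative to all genes, percentile 99.97 of random lists). Ciita (1.11-fold lower, 1.02 to 1.20) and H2-DMb1 (1.41-fold higher, 1.35 to 1.46) stood lowest in the list. Cd74 (3.50-fold higher, 3.46 to 3.53) and H2-Eb1 (3.34-fold higher, 3.29 to 3.39) stood highest. Proliferation genes had 0 of 25 measured members higher and 24 lower in this class (median log2 fold -2.27, counting interval -2.43 to -2.01, -1.86 relative to all genes, percentile 0 of random lists). Macrophage or monocyte-like cells held Cmss1 (16.0-fold higher, 15.5 to 16.5), Id3 (13.6-fold higher, 11.4 to 16.3) and Slamf7 (9.17-fold higher, 8.12 to 10.4). Marco, Mmp9 (45.6-fold lower, 38.4 to 54.5) and Lyve1 stood lowest. Cmss1 was higher together with the ribosomal RNA-like gene Gm42418 (31993 CPM against 2184 CPM), and shared reads were not tested for it here or in later comparisons. In neutrophil-like cells Cmss1 (31.1-fold higher, 27.6 to 35.1) and Bcl2a1b (17.4-fold higher, 14.9 to 20.5) stood highest, and the granule genes Elane (at least 106-fold lower) and Mpo (274-fold lower, 49.0 to 10838) lowest. Neutrophil activation genes had 13 of 19 measured members higher and 4 lower (median log2 fold 1.47, counting interval 1.35 to 1.61, 1.64 relative to all genes, percentile 99.99 of random lists). Ltf (7.49-fold lower, 6.86 to 8.20) and Mmp8 (4.59-fold lower, 3.92 to 5.41) stood lowest in the list. Cd14 (8.26-fold higher, 7.67 to 8.90) and Siglecf (6.96-fold higher, 4.77 to 10.3) stood highest. Regulatory T cell genes in T-like cells had 9 of 12 measured members higher and 1 lower (median log2 fold 1.38, counting interval 1.03 to 1.67, percentile 100 of random lists). Il10 (1.60-fold lower, 0.593 to 4.73) and Ctla4 (1.07-fold higher, 0.938 to 1.23) stood lowest in the list. Areg (16.3-fold higher, 9.95 to 28.4) and Il1rl1 (6.87-fold higher, 4.76 to 10.2) stood highest. A Foxp3 UMI was seen in 15.1% of 106 T-like cells with the inhibitor and 7.76% of 219 with vehicle after thinning to 1000 UMIs per cell, and in 0 of 158 and 0.148% of 1350 epithelial-like cells. T-like cells also held Mpp7 (20.05-fold higher, 13.7 to 30.5) and Ccl8 (15.9-fold lower, 7.48 to 40.2).

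The comparison of 5 weeks of MRTX1133 with the vehicle library addresses tumours that the labels call resistant. Vehicle had been given for 1 week, so treatment and time cannot be separated. ERK output genes were lower in epithelial-like cells, interferon genes were lower in macrophage or monocyte-like cells, and neutrophil-like cells made up 46.4% (2330 of 5018 leukocytes) against 20.5% (714 of 3479), a log2 ratio of 1.18 (1.07 to 1.28). T-like cells were 8.07% (405 of 5018) against 6.44%, a log2 ratio of 0.33 (0.10 to 0.55). Macrophage or monocyte-like cells were 29.3% (1471 of 5018) against 54.7%, a log2 ratio of -0.90 (-0.97 to -0.82). Of 1026 epithelial-like cells at 5 weeks, 550 and 352 lay in 2 clusters that held 162 and 33 of the 1380 vehicle cells. The larger was named on 3 of 12 markers, with 0 among its leading genes. By marker score the class fell from 14.8% to 7.96% of kept cells (vehicle 20.6% to 18.2%). Median depth was 6154 UMIs (vehicle 26340). The median of all genes was shifted by -0.73 in epithelial-like, -0.21 in fibroblast-like, -0.32 in macrophage or monocyte-like, 0.14 in neutrophil-like and -0.20 in T-like cells, and in epithelial-like cells the median fold ran from -0.30 in the genes with the shortest gene bodies, of 4 groups by length, to -1.12 in those with the longest.

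ERK output genes had 0 of 20 measured members higher and 18 lower (median log2 fold -1.79, counting interval -1.88 to -1.71, -1.06 relative to all genes, percentile 0 of random lists). Dusp5 (8.06-fold lower, 7.40 to 8.79) and Epha4 (5.30-fold lower, 4.38 to 6.47) stood lowest in the list. Ccnd1 (1.39-fold lower, 1.35 to 1.44) and Ier3 (1.42-fold lower, 1.36 to 1.48) stood highest. Dusp6 was 4.16-fold lower (3.71 to 4.68). Hypoxia and glycolysis genes had 0 of 17 measured members higher and 13 lower (median log2 fold -2.38, counting interval -2.49 to -2.18, -1.65 relative to all genes, percentile 0 of random lists). Hk2 (16.1-fold lower, 14.6 to 17.8) and Adm (15.8-fold lower, 12.4 to 20.5) stood lowest in the list. Eno1 (1.25-fold lower, 1.19 to 1.30) and Ldha (1.33-fold lower, 1.30 to 1.37) stood highest. YAP and TEAD target genes had 1 of 20 measured members higher and 17 lower (median log2 fold -1.19, counting interval -1.30 to -1.10, -0.46 relative to all genes, percentile 2.60 of random lists). Ankrd1 (6.60-fold lower, 6.30 to 6.92) and Fgf2 (6.15-fold lower, 4.32 to 9.07) stood lowest in the list. Tgfb2 (1.58-fold higher, 1.13 to 2.18) and Nuak2 (1.04-fold lower, 0.724 to 1.52) stood highest. Epithelial state genes had 6 of 16 measured members higher and 2 lower (median log2 fold 0.47, counting interval 0.14 to 0.54, 1.20 relative to all genes, percentile 99.8 of random lists). Elf3 (2.42-fold lower, 2.17 to 2.70) and Ocln (2.13-fold lower, 1.72 to 2.67) stood lowest in the list. Tacstd2 (69.6-fold higher, 35.8 to 155) and Epcam (4.40-fold higher, 4.20 to 4.61) stood highest. MHC class I genes had 11 of 18 measured members higher and 1 lower (median log2 fold 0.59, counting interval 0.38 to 0.89, 1.32 relative to all genes, percentile 99.99 of random lists). Nlrc5 (4.40-fold lower, 1.42 to 22.1) and Tapbp (1.12-fold lower, 0.988 to 1.26) stood lowest in the list. H2-Q4 (2.97-fold higher, 1.55 to 5.60) and Psmb10 (2.54-fold higher, 2.23 to 2.89) stood highest.

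By single gene in epithelial-like cells, Ly6d (169-fold higher, 103 to 297), S100g (173-fold higher, 102 to 317), Cck (115-fold higher, 99.5 to 132), Cmss1 (31.8-fold higher, 31.1 to 32.5) and Il31ra (29.8-fold higher, 25.9 to 34.6) stood highest and Prdm1 (24.6-fold lower, 17.5 to 35.8), Pgf (19.1-fold lower, 15.3 to 24.2), Unc13c (17.5-fold lower, 14.9 to 20.7), Ndst3 (18.0-fold lower, 14.8 to 21.98) and Hk2 (16.1-fold lower, 14.6 to 17.8) lowest. Mki67 was 1.01-fold lower (0.904 to 1.14) and Kras 1.13-fold lower (1.11 to 1.16). Relative to all genes the log2 fold of Kras was 0.55.

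The other classes held different cells as well. The fibroblast-like cluster led by collagen genes made up 33.7% against 94.7% with vehicle and the one led by Cfd and Car3 64.5% against 2.54%. Of macrophage or monocyte-like cells, 63.5% and 33.9% at 5 weeks lay in 2 clusters that held 3.42% and 0.21% with vehicle. Of neutrophil-like cells, 82.7% lay in a cluster that held 14.8% with vehicle. Inflammatory CAF genes of fibroblast-like cells had 1 of 17 measured members higher and 16 lower (median log2 fold -1.42, counting interval -1.69 to -1.31, -1.20 relative to all genes, percentile 0 of random lists). Col14a1 (8.35-fold lower, 6.96 to 10.1) and Il6 (4.47-fold lower, 3.72 to 5.42) stood lowest in the list. Ccl11 (1.56-fold higher, 1.33 to 1.83) and C3 (1.58-fold lower, 1.51 to 1.65) stood highest. Collagen and matrix genes had 0 of 16 measured members higher and 11 lower (median log2 fold -1.23, counting interval -1.34 to -1.18, -1.02 relative to all genes, percentile 0 of random lists). Col1a2 (5.96-fold lower, 5.82 to 6.10) and Col3a1 (4.81-fold lower, 4.71 to 4.91) stood lowest in the list. Col4a2 (1.18-fold higher, 1.10 to 1.26) and Col4a1 (1.14-fold higher, 1.08 to 1.19) stood highest. The fibroblast-like genes furthest apart were Cfd (at least 1652-fold higher), Cmss1 (66.3-fold higher, 63.2 to 69.6) and Camk1d (44.0-fold higher, 41.1 to 47.2), against Top2a (64.8-fold lower, 27.7 to 199.9), Rxfp1 (at least 30.1-fold lower) and C77080 (29.0-fold lower, 21.1 to 41.1).

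Type I interferon genes of macrophage or monocyte-like cells had 0 of 19 measured members higher and 18 lower (median log2 fold -2.23, counting interval -2.40 to -1.91, -1.91 relative to all genes, percentile 0 of random lists). Ifi27l2a (13.4-fold lower, 12.6 to 14.1) and Rtp4 (13.3-fold lower, 9.79 to 18.6) stood lowest in the list. Bst2 (1.03-fold lower, 0.964 to 1.09) and Isg15 (1.72-fold lower, 1.48 to 2.01) stood highest. Tumour-associated macrophage genes had 3 of 18 measured members higher and 10 lower (median log2 fold -0.76, counting interval -0.79 to -0.71, -0.45 relative to all genes, percentile 0.0800 of random lists). Retnla (181-fold lower, 77.4 to 560.3) and Lyve1 (39.8-fold lower, 35.2 to 45.1) stood lowest in the list. Chil3 (5.84-fold higher, 5.75 to 5.93) and Apoe (2.38-fold higher, 2.37 to 2.39) stood highest. Apart from those lists, Cmss1 (24.9-fold higher, 24.1 to 25.7), Il31ra (14.4-fold higher, 12.6 to 16.6) and Jaml (9.44-fold higher, 9.002 to 9.91) stood highest, and Vsig4 (87.2-fold lower, 62.5 to 125), Ccl8 (51.9-fold lower, 48.2 to 56.0) and Ednrb (54.7-fold lower, 47.2 to 63.6) lowest. Neutrophil-like cells held Cmss1 (61.9-fold higher, 55.2 to 69.6) and Cdk8 (30.5-fold higher, 25.6 to 36.7), with Ccl8 (175-fold lower, 94.3 to 368) and Mpo (47.3-fold lower, 36.6 to 62.3) at the other end. In T-like cells Cmss1 (55.1-fold higher, 46.9 to 65.3) and Cdk8 (31.8-fold higher, 24.8 to 41.5) stood highest and the chemokine genes Ccl1 (at least 121-fold lower) and Ccl8 (107-fold lower, 40.8 to 399) lowest. Regulatory T cell genes had 1 of 12 measured members higher and 8 lower (median log2 fold -1.36, counting interval -1.70 to -1.17, -1.16 relative to all genes, percentile 0.01 of random lists). Foxp3 (7.49-fold lower, 4.97 to 11.5) and Ikzf2 (6.11-fold lower, 5.40 to 6.91) stood lowest in the list. Areg (1.60-fold higher, 0.943 to 2.86) and Lrrc32 (1.13-fold higher, 0.360 to 4.68) stood highest. T cell checkpoint genes had 1 of 14 measured members higher and 10 lower (median log2 fold -1.11, counting interval -1.24 to -0.84, -0.91 relative to all genes, percentile 0.0300 of random lists). Cd244 (6.64-fold lower, 2.07 to 24.7) and Lag3 (5.81-fold lower, 2.27 to 16.0) stood lowest in the list. Nr4a2 (1.51-fold higher, 1.12 to 2.06) and Pdcd1 (1.38-fold higher, 0.920 to 2.14) stood highest. A Foxp3 UMI was seen in 2.01% of 399 T-like cells at 5 weeks, against 7.76% of 219 with vehicle, and in 0 of 949 epithelial-like cells at 5 weeks.

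**Figure D1:**
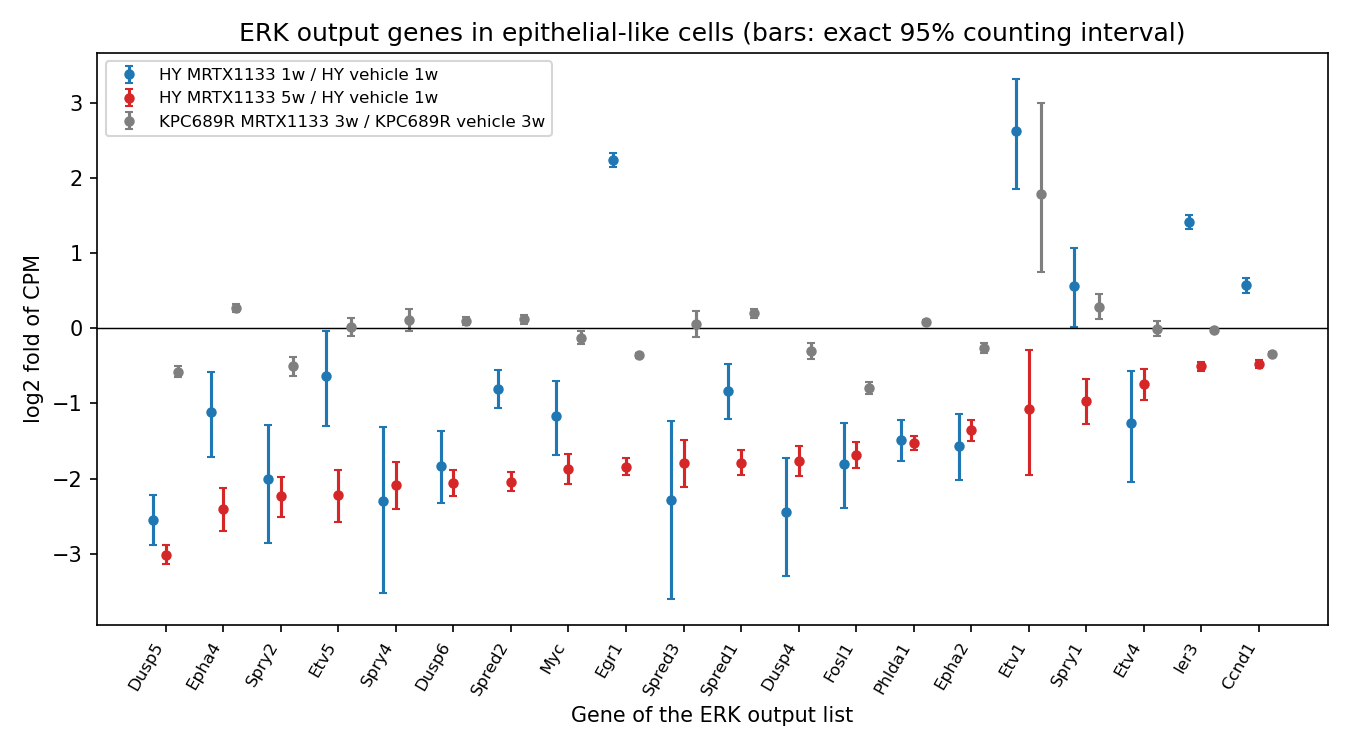
Log2 fold of CPM (vertical axis) of each gene of the ERK output list (horizontal axis) in epithelial-like cells, for 1 week and 5 weeks of MRTX1133 against vehicle in HY tumours and for MRTX1133 against vehicle in KPC689R tumours. Points are single libraries against single libraries and bars are exact 95% counting intervals. Dusp5 lies at -2.54 and -3.01 in the HY comparisons and at -0.58 in the KPC689R comparison.

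The comparison of 5 weeks with 1 week of MRTX1133 in HY tumours sets the late against the early library. Neutrophil-like cells were 46.4% against 7.85% of leukocytes, a log2 ratio of 2.56 (2.38 to 2.75). T-like cells were 8.07% against 3.65%, a log2 ratio of 1.14 (0.84 to 1.44). The epithelial-like class again had different cells, with 122 of 160 cells in the duct-gene cluster at 1 week and 7 of 1026 at 5 weeks. Macrophage or monocyte-like cells shared almost no cluster: the 2 largest at 5 weeks held 63.5% and 33.9%, against 1.61% and 0% at 1 week. The T-like cluster led by Ikzf2 and Ctla4 held 4.20% and 49.5%, and the fibroblast-like cluster led by Cfd and Car3 64.5% and 43.8%. The median of all genes was shifted by -0.67 in epithelial-like, -0.17 in fibroblast-like and 0.41 in neutrophil-like cells. ERK output genes had 1 of 20 measured members higher and 10 lower (median log2 fold -0.58, counting interval -0.84 to -0.36, 0.09 relative to all genes, -0.09 without the duct-gene cluster, percentile 69.5 of random lists), so the direction depends on the scaling. Egr1 (16.8-fold lower, 15.2 to 18.6) and Etv1 (12.9-fold lower, 6.27 to 27.0) stood lowest in the list. Dusp4 (1.61-fold higher, 0.955 to 2.92) and Etv4 (1.42-fold higher, 0.871 to 2.49) stood highest. In fibroblast-like cells, myofibroblast genes had 14 of 15 measured members higher and 0 lower (median log2 fold 2.34, counting interval 2.12 to 2.63, 2.51 relative to all genes, percentile 100 of random lists). Fap (1.11-fold higher, 0.925 to 1.34) and Inhba (1.52-fold higher, 1.24 to 1.87) stood lowest in the list. Tagln (18.5-fold higher, 15.2 to 22.7) and Acta2 (15.5-fold higher, 12.0 to 20.4) stood highest. In macrophage or monocyte-like cells, MHC class II genes had 0 of 7 measured members higher and 6 lower (median log2 fold -2.19, counting interval -2.21 to -2.16, percentile 0 of random lists). Ciita (5.89-fold lower, 5.07 to 6.86) and H2-Eb1 (5.85-fold lower, 5.75 to 5.96) stood lowest in the list. H2-DMa (1.37-fold lower, 1.32 to 1.41) and H2-DMb1 (2.57-fold lower, 2.45 to 2.69) stood highest. Regulatory T cell genes in T-like cells had 0 of 12 measured members higher and 11 lower (median log2 fold -3.06, counting interval -3.29 to -2.74, percentile 0 of random lists). Il1rl1 (35.2-fold lower, 22.6 to 57.5) and Il2ra (15.3-fold lower, 11.3 to 21.2) stood lowest in the list. Il10 (1.29-fold lower, 0.462 to 3.14) and Ctla4 (2.41-fold lower, 2.13 to 2.73) stood highest. Epithelial-like single genes furthest apart were Tff1 (533-fold higher, 182 to 2582), Cck (at least 222-fold higher) and Npy (189-fold higher, 64.7 to 918) and, lower at 5 weeks, Csmd1 (at least 377-fold lower), Angpt1 (487-fold lower, 206 to 1513) and Ces1d (273-fold lower, 177 to 445).

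The comparison of MRTX1133 with vehicle in KPC689R tumours asks how tumours already resistant, by the labels, differ under the inhibitor. The ERK output median of epithelial-like cells lay within counting error of 0, but at -0.0614 with median-ratio scaling and -0.189 after thinning to 1000 UMIs per cell. T-like cells were 35.04% (2133 of 6087 leukocytes) against 26.5% (1028 of 3882), a log2 ratio of 0.40 (0.31 to 0.49). Macrophage or monocyte-like cells were 39.8% (2422 of 6087) against 51.3% (1992 of 3882), a log2 ratio of -0.37 (-0.43 to -0.30). Neutrophil-like cells were 4.37% (266 of 6087) against 3.32% (129 of 3882), a log2 ratio of 0.40 (0.10 to 0.69). That direction is lower, at -0.78, when each cell is classed by its highest marker score, and -1.12 when an unnamed cluster with neutrophil genes is counted in. Of T-like cells thinned to 1000 UMIs, 50.4% of 2118 with the inhibitor and 42.1% of 1026 with vehicle had a Cd8a or Cd8b1 UMI, against 0.216% of 1851 and 0.293% of 683 epithelial-like cells. A Foxp3 UMI was seen in 2.74% and 7.80% of them. Leukocytes had 38.6 CPM of the Y-linked genes with the inhibitor and 247 CPM with vehicle. The all-gene shift exceeded 0.1 only in neutrophil-like cells (-0.15) among the 5 classes described.

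ERK output genes had 1 of 20 measured members higher and 1 lower (median log2 fold 0.006, counting interval -0.04 to 0.05, percentile 15.8 of random lists). Fosl1 (1.73-fold lower, 1.64 to 1.83) and Dusp5 (1.49-fold lower, 1.42 to 1.57) stood lowest in the list. Etv1 (3.44-fold higher, 1.68 to 7.96) and Spry1 (1.22-fold higher, 1.09 to 1.37) stood highest. Dusp6 was 1.07-fold higher (1.03 to 1.11). Proliferation genes had 0 of 25 measured members higher and 4 lower (median log2 fold -0.38, counting interval -0.42 to -0.32, percentile 0 of random lists). Mcm5 (1.73-fold lower, 1.54 to 1.93) and Ccne1 (1.67-fold lower, 1.40 to 1.99) stood lowest in the list. Tyms (1.16-fold higher, 1.09 to 1.22) and Tpx2 (1.06-fold lower, 1.01 to 1.12) stood highest. The 2 largest clusters held 66.9% and 26.5% of the class against 56.5% and 38.8% with vehicle. MHC class I genes had 0 of 18 measured members higher and 6 lower (median log2 fold -0.47, counting interval -0.51 to -0.42, percentile 0 of random lists). H2-Q4 (2.58-fold lower, 2.28 to 2.94) and H2-Q6 (2.49-fold lower, 2.01 to 3.08) stood lowest in the list. Erap1 (1.005-fold higher, 0.919 to 1.10) and H2-T23 (1.07-fold lower, 1.02 to 1.12) stood highest. Normal duct and lineage genes had 8 of 14 measured members higher and 0 lower (median log2 fold 0.73, counting interval 0.63 to 0.79, 0.65 without the duct-gene cluster, percentile 100 of random lists). Sox9 (1.09-fold lower, 1.06 to 1.12) and Pdx1 (1.08-fold higher, 0.9999 to 1.16) stood lowest in the list. Dcdc2a (3.90-fold higher, 3.46 to 4.42) and Bhlha15 (3.72-fold higher, 0.827 to 34.2) stood highest. Single genes of the epithelial-like class were Ppargc1a (4.31-fold higher, 3.98 to 4.68), Mmp3 (3.23-fold higher, 3.14 to 3.32), S100a3 (2.49-fold higher, 2.42 to 2.56), Eya2 (2.42-fold higher, 2.26 to 2.58) and Mgst1 (2.09-fold higher, 2.00 to 2.19), and on the other side Hist1h2ap (6.86-fold lower, 6.42 to 7.33), Uba52 (4.97-fold lower, 4.86 to 5.09), Gstp1 (4.18-fold lower, 3.88 to 4.51), Hmga1 (3.105-fold lower, 2.92 to 3.31) and Nme2 (2.63-fold lower, 2.496 to 2.78). Ppargc1a encodes a coactivator of mitochondrial biogenesis and Mmp3 a matrix metalloproteinase.

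Of fibroblast-like cells, 41.8% against 2.62% with vehicle lay in a cluster led by Clec3b and Gsn, and 51.0% against 89.5% in that led by collagen genes. MHC class II genes of fibroblast-like cells had 0 of 7 measured members higher and 7 lower (median log2 fold -1.49, counting interval -1.57 to -1.35, percentile 0 of random lists). H2-DMa (3.08-fold lower, 2.34 to 4.09) and H2-Aa (3.01-fold lower, 2.72 to 3.33) stood lowest in the list. H2-DMb1 (2.02-fold lower, 1.62 to 2.54) and H2-Ab1 (2.501-fold lower, 2.27 to 2.75) stood highest. Interferon gamma genes had 0 of 20 measured members higher and 14 lower (median log2 fold -0.71, counting interval -0.90 to -0.62, percentile 0 of random lists). Tgtp2 (3.53-fold lower, 2.41 to 5.26) and Gbp4 (3.46-fold lower, 2.74 to 4.41) stood lowest in the list. Socs1 (1.49-fold higher, 1.28 to 1.74) and Gbp9 (1.07-fold lower, 0.718 to 1.60) stood highest. Proliferation genes had 16 of 25 measured members higher and 0 lower (median log2 fold 0.85, counting interval 0.71 to 1.13, percentile 100 of random lists). Ccne1 (1.39-fold lower, 0.994 to 1.95) and Mcm6 (1.17-fold lower, 0.921 to 1.48) stood lowest in the list. Ccna2 (4.19-fold higher, 2.46 to 7.60) and Cenpf (3.56-fold higher, 2.49 to 5.23) stood highest. By single gene, Inmt (22.1-fold higher, 13.5 to 39.0), Abca8a (7.96-fold higher, 6.57 to 9.72) and Chrm3 (8.10-fold higher, 6.44 to 10.3) stood highest and Serpinb2 (9.39-fold lower, 7.14 to 12.5), Col6a5 (6.46-fold lower, 5.56 to 7.54) and Uba52 (4.24-fold lower, 3.96 to 4.54) lowest.

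Interferon gamma genes of neutrophil-like cells had 0 of 16 measured members higher and 15 lower (median log2 fold -1.44, counting interval -1.83 to -1.13, -1.28 relative to all genes, percentile 0 of random lists). Socs1 (33.0-fold lower, 4.96 to 1402) and Gbp4 (6.35-fold lower, 1.83 to 27.7) stood lowest in the list. Iigp1 (1.13-fold lower, 0.254 to 4.04) and Irf8 (1.52-fold lower, 0.455 to 4.62) stood highest. These are 266 and 129 cells, and the class leaves out the unnamed cluster with neutrophil genes, which held 140 cells with the inhibitor and 491 with vehicle. With that cluster counted in, 1 of 19 measured members was higher and 9 lower, with a median of -0.51. Clusters led by Retnlg and Ngp and by Camp held 16.9% against 2.33% and 6.39% against 2.33% of the class. Neutrophil-like cells held Smc2 (at least 13.5-fold higher) and Hist1h1b (25.7-fold higher, 9.92 to 95.1), with Prl2c3 (at least 26.2-fold lower) and Rcan1 (24.9-fold lower, 9.96 to 80.0) lowest. In macrophage or monocyte-like cells Klf2 (2.46-fold higher, 2.37 to 2.55), H2-M2 (2.19-fold higher, 2.08 to 2.31) and Ear2 (1.92-fold higher, 1.81 to 2.04) stood highest, and Uba52 (3.87-fold lower, 3.74 to 3.99), Inhba (2.58-fold lower, 2.5 to 2.66) and Cxcl3 (2.61-fold lower, 2.47 to 2.76) lowest. Regulatory T cell genes had 0 of 12 measured members higher and 4 lower in T-like cells (median log2 fold -0.47, counting interval -0.57 to -0.42, percentile 0 of random lists), of which 10.2% against 21.0% lay in the cluster led by Ikzf2 and Ctla4. Areg (3.48-fold lower, 3.27 to 3.70) and Il10 (2.76-fold lower, 2.28 to 3.34) stood lowest in the list. Ctla4 (1.10-fold lower, 1.08 to 1.13) and Ikzf4 (1.14-fold lower, 1.06 to 1.22) stood highest. T-like cells also held Chn2 (1.76-fold higher, 1.66 to 1.87) and the chemokine gene Xcl1 (1.67-fold higher, 1.57 to 1.77), with Hist1h2ap (5.53-fold lower, 5.25 to 5.83) and Uba52 (4.07-fold lower, 3.95 to 4.20) lowest.

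The comparison of aCTLA4 with isotype in MRTX1133-treated HY tumours asks what checkpoint blockade adds. T-like cells were 5.27% (55 of 1043 leukocytes) against 2.71% (37 of 1364), a log2 ratio of 0.96 (0.37 to 1.55). B-like cells were 15.2% (159 of 1043) against 3.37% (46 of 1364), a log2 ratio of 2.18 (1.72 to 2.64). Type I interferon genes were lower in macrophage or monocyte-like and neutrophil-like cells. The epithelial-like class held 72 and 68 cells, with an all-gene shift of 0.17. Only 2 members of the interferon gamma list reached 10 UMIs there, too few for a median, and fibroblast-like cells were 18 and 12, too few for any list. The libraries also differ in Y-linked and Xist transcripts.

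Type I interferon genes had 0 of 19 measured members higher and 15 lower in macrophage or monocyte-like cells (median log2 fold -0.91, counting interval -1.09 to -0.77, percentile 0 of random lists). Ifit3b (12.9-fold lower, 2.02 to 540.1) and Usp18 (2.98-fold lower, 1.90 to 4.83) stood lowest in the list. Mx1 (1.17-fold lower, 0.776 to 1.78) and Oas1a (1.21-fold lower, 0.973 to 1.51) stood highest. In neutrophil-like cells they had 0 of 15 measured members higher and 12 lower (median log2 fold -1.22, counting interval -1.49 to -0.95, percentile 0 of random lists). Ifit3 (6.62-fold lower, 1.95 to 34.9) and Bst2 (4.30-fold lower, 2.78 to 6.88) stood lowest in the list. Cmpk2 (1.003-fold higher, 0.526 to 1.92) and Oasl2 (1.36-fold lower, 1.20 to 1.53) stood highest. Of the 55 and 37 T-like cells, 76.4% and 62.2% lay in a cluster led by Lef1. In them naive and memory T cell genes had 7 of 10 measured members higher and 0 lower (median log2 fold 0.87, counting interval 0.65 to 1.10, percentile 99.98 of random lists). Il7r (1.24-fold lower, 1.02 to 1.51) and S1pr1 (1.03-fold higher, 0.726 to 1.49) stood lowest in the list. Lef1 (4.71-fold higher, 3.30 to 6.93) and Ccr7 (3.91-fold higher, 2.13 to 7.86) stood highest. p53 target genes of epithelial-like cells had 9 of 11 measured members higher and 2 lower (median log2 fold 1.25, counting interval 0.77 to 1.75, 1.08 relative to all genes, percentile 99.99 of random lists). Phlda3 (5.68-fold lower, 1.85 to 23.2) and Tnfrsf10b (1.56-fold lower, 0.448 to 5.61) stood lowest in the list. Gdf15 (9.74-fold higher, 1.46 to 414) and Cdkn1a (5.38-fold higher, 2.85 to 11.2) stood highest. Cdkn1a encodes a cell cycle inhibitor. Dissociation stress genes had 12 of 18 measured members higher and 0 lower beside them (median log2 fold 0.98, counting interval 0.75 to 1.17, 0.81 relative to all genes, percentile 100 of random lists). Single genes were Nppb (at least 33.7-fold higher), Retnlg (45.8-fold higher, 23.9 to 101), Pmvk (33.5-fold higher, 19.0 to 65.1), Dlg2 (at least 21.0-fold higher) and Mgp (at least 14.2-fold higher), and lower Gnb1l (62.8-fold lower, 10.7 to 2531), Arhgap39 (26.7-fold lower, 8.71 to 133), Fastkd1 (21.4-fold lower, 6.89 to 107), C3 (14.4-fold lower, 5.22 to 55.1) and Cxcl5 (11.3-fold lower, 4.87 to 32.4). Macrophage or monocyte-like cells held Vcam1 (3.18-fold higher, 2.87 to 3.52), Jaml (2.41-fold higher, 2.20 to 2.63) and Chil3 (2.02-fold higher, 1.97 to 2.07), with Saa3 (2.71-fold lower, 2.58 to 2.85), Mir155hg (2.54-fold lower, 2.20 to 2.94) and Ccl8 (2.46-fold lower, 2.12 to 2.85) lowest. Neutrophil-like cells held Ctsk (85.0-fold higher, 38.8 to 233) and Ckb (77.04-fold higher, 21.0 to 642), with Ccl2 (6.72-fold lower, 4.69 to 9.89) and Ifi27l2a (3.23-fold lower, 2.56 to 4.11) lowest.

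The comparison of CDK8i with isotype asks what CDK8 inhibition adds to MRTX1133. T-like cells were 4.79% (82 of 1712 leukocytes) against 2.71%, a log2 ratio of 0.82 (0.27 to 1.37). B-like cells were 8.94% (153 of 1712) against 3.37%, a log2 ratio of 1.41 (0.94 to 1.87). Interferon genes were lower in macrophage or monocyte-like and neutrophil-like cells, and chemokine genes in epithelial-like cells. Neutrophil-like chemokine genes were lower too with the unnamed neutrophil-gene cluster counted (median log2 fold -0.67, 0 of 14 measured members higher and 7 lower). The leukocyte classes differed in clusters: 1 cluster held 27.5% against 56.5% of neutrophil-like and another 56.5% against 34.7% of macrophage or monocyte-like cells. The all-gene shift was 0.20 in the 141 and 68 epithelial-like cells and 0.12 in neutrophil-like cells. Again 2 interferon gamma members were measured in epithelial-like cells, so no median is given.

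Chemokine and cytokine genes of epithelial-like cells had 0 of 11 measured members higher and 8 lower (median log2 fold -1.30, counting interval -2.16 to -0.93, -1.498 relative to all genes, percentile 0 of random lists). Cxcl3 (21.5-fold lower, 3.18 to 918) and Il1b (13.2-fold lower, 7.80 to 23.8) stood lowest in the list. Cxcl16 (1.30-fold higher, 0.798 to 2.16) and Tnf (1.07-fold lower, 0.321 to 3.26) stood highest. Cxcl2, a neutrophil chemoattractant gene, was 12.9-fold lower (8.57 to 20.02). Without free RNA subtraction, leukocyte transcripts are not excluded. Single genes were Tff2 (31.1-fold higher, 12.0 to 115), S100g (37.4-fold higher, 6.49 to 1500.3), Tff1 (6.08-fold higher, 5.09 to 7.31), Ramp3 (12.0-fold higher, 4.53 to 45.1) and H2afz (3.83-fold higher, 3.48 to 4.23), and lower Prkg1 (at least 21.5-fold lower), Fastkd1 (43.0-fold lower, 11.3 to 365), Gnb1l (42.1-fold lower, 11.01 to 357), C3 (38.5-fold lower, 10.0 to 328) and Arhgap39 (21.5-fold lower, 8.71 to 68.5). Tff1 and Tff2 encode trefoil peptides.

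Type I interferon genes had 0 of 19 measured members higher and 18 lower in macrophage or monocyte-like cells (median log2 fold -1.48, counting interval -1.61 to -1.27, percentile 0 of random lists). Ifit3b (4.86-fold lower, 1.58 to 19.8) and Ifit1bl1 (at least 4.19-fold lower) stood lowest in the list. Oas1a (1.45-fold lower, 1.18 to 1.78) and Bst2 (1.55-fold lower, 1.43 to 1.68) stood highest. Interferon gamma genes had 0 of 18 measured members higher and 12 lower (median log2 fold -0.85, counting interval -0.99 to -0.61, percentile 0 of random lists). Iigp1 (13.9-fold lower, 5.66 to 44.5) and Gbp2 (2.86-fold lower, 2.26 to 3.64) stood lowest in the list. Cd274 (1.44-fold higher, 1.33 to 1.57) and Irf8 (1.12-fold higher, 1.03 to 1.21) stood highest. In neutrophil-like cells, type I interferon genes had 0 of 15 measured members higher and 15 lower (median log2 fold -2.51, counting interval -3.04 to -2.32, -2.64 relative to all genes, percentile 0 of random lists). Ifit1 (41.8-fold lower, 11.2 to 351) and Usp18 (26.8-fold lower, 4.38 to 1099) stood lowest in the list. Oasl2 (2.14-fold lower, 1.87 to 2.46) and Ifit2 (2.78-fold lower, 0.932 to 9.98) stood highest. Macrophage or monocyte-like cells held Cd163 (3.89-fold higher, 3.21 to 4.73), Uba52 (3.39-fold higher, 3.17 to 3.62) and Cirbp (3.43-fold higher, 2.89 to 4.10), with Ccl24 (10.7-fold lower, 9.60 to 12.0), Saa3 (5.16-fold lower, 4.89 to 5.45) and Ckap2l (3.37-fold lower, 2.97 to 3.84) lowest. Neutrophil-like cells held Hist1h2ap (11.1-fold higher, 8.73 to 14.4) and Cpa6 (16.0-fold higher, 8.20 to 35.6), with Rsad2 (24.5-fold lower, 12.7 to 54.4) and Ifi27l2a (7.14-fold lower, 5.21 to 10.00) lowest.

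The comparison of CDK8i plus aCTLA4 with isotype asks what both add. T-like cells were 8.64% (210 of 2431 leukocytes) against 2.71%, a log2 ratio of 1.67 (1.18 to 2.17). B-like cells were 15.5% (376 of 2431) against 3.37%, a log2 ratio of 2.20 (1.77 to 2.63). Neutrophil-like cells were 23.2% (565 of 2431) against 36.6% (499 of 1364), a log2 ratio of -0.65 (-0.80 to -0.51). The isotype library had the lowest T-like and B-like shares of the HY libraries, and MRTX1133 alone for 5 weeks had 8.07% and 9.45%. In the 80 and 68 epithelial-like cells ERK output genes were higher and proliferation genes lower. The all-gene shift was 0.54 in epithelial-like, 0.20 in neutrophil-like and 0.18 in T-like cells. Of the 80 epithelial-like cells 15 lay in the duct-gene cluster, against 3 of 68.

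Interferon gamma genes of epithelial-like cells had 3 of 4 measured members higher and 1 lower (median log2 fold 1.91, counting interval 0.61 to 2.85, 1.37 relative to all genes, percentile 99.2 of random lists), a median over few members. Cxcl10 (2.17-fold lower, 0.580 to 9.83) and Stat1 (2.77-fold higher, 0.691 to 15.9) stood lowest in the list. Irf1 (7.52-fold higher, 3.42 to 19.5) and Cd274 (5.08-fold higher, 1.11 to 47.1) stood highest. ERK output genes had 15 of 19 measured members higher and 1 lower (median log2 fold 1.36, counting interval 0.96 to 1.80, 0.82 relative to all genes, 1.40 without the duct-gene cluster, percentile 99.9 of random lists). Spred3 (5.78-fold lower, 1.65 to 30.9) and Spry2 (1.35-fold lower, 0.481 to 3.95) stood lowest in the list. Ier3 (7.90-fold higher, 6.19 to 10.2) and Dusp4 (6.92-fold higher, 2.44 to 27.1) stood highest. Dusp6 was 3.60-fold higher (1.76 to 8.09). Proliferation genes had 1 of 16 measured members higher and 14 lower (median log2 fold -2.51, counting interval -2.68 to -1.53, -3.05 relative to all genes, -2.33 without the duct-gene cluster, percentile 0 of random lists). Birc5 (17.3-fold lower, 2.69 to 727) and Cenpf (13-fold lower, 1.92 to 556) stood lowest in the list. Pcna (1.62-fold higher, 0.759 to 3.60) and Mcm7 (1.20-fold lower, 0.613 to 2.35) stood highest. Dissociation stress genes had 15 of 18 measured members higher and 0 lower (median log2 fold 2.16, counting interval 1.97 to 2.48, 1.62 relative to all genes, 1.91 without the duct-gene cluster, percentile 100 of random lists). Single genes were Tff3 (at least 32.9-fold higher), Muc2 (at least 29.5-fold higher) and Clca1 (114-fold higher, 20.2 to 4558), goblet cell genes with UMIs in at most 4 of the 80 cells, with Cadm2 (105-fold higher, 18.5 to 4193) and Erbb4 (96.9-fold higher, 17.0 to 3865), and lower Rbp4 (17.6-fold lower, 10.3 to 32.6), Gnb1l (25.5-fold lower, 6.67 to 216), Arhgap39 (16.2-fold lower, 6.03 to 61.6), Sprr2k (20.04-fold lower, 5.17 to 172) and Flvcr1 (9.75-fold lower, 3.88 to 31.5).

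MHC class II genes had 6 of 7 measured members higher and 0 lower in macrophage or monocyte-like cells (median log2 fold 0.87, counting interval 0.86 to 0.90, percentile 100 of random lists). H2-DMa (1.40-fold higher, 1.33 to 1.47) and H2-DMb1 (1.52-fold higher, 1.43 to 1.60) stood lowest in the list. Ciita (2.96-fold higher, 2.54 to 3.47) and H2-Ab1 (2.00-fold higher, 1.96 to 2.03) stood highest. Type I interferon genes of neutrophil-like cells had 0 of 15 measured members higher and 14 lower (median log2 fold -1.29, counting interval -1.73 to -1.05, -1.49 relative to all genes, percentile 0 of random lists), and the same isotype library is the comparator with aCTLA4 or CDK8i alone. In T-like cells naive and memory genes had 7 of 10 measured members higher and 1 lower (median log2 fold 1.34, counting interval 1.02 to 1.66, 1.15 relative to all genes, percentile 100 of random lists). Il7r (1.59-fold lower, 1.33 to 1.88) and S1pr1 (1.36-fold lower, 0.976 to 1.85) stood lowest in the list. Lef1 (7.44-fold higher, 5.30 to 10.8) and Ccr7 (4.27-fold higher, 2.41 to 8.34) stood highest. Macrophage or monocyte-like cells held Retnla (642-fold higher, 115 to 25400), Cadm1 (4.95-fold higher, 4.18 to 5.90) and Dcstamp (4.75-fold higher, 4.07 to 5.56), with Ccl24 (9.90-fold lower, 8.96 to 10.96), Il31ra (5.12-fold lower, 4.46 to 5.88) and Mt2 (4.75-fold lower, 4.31 to 5.23) lowest. Neutrophil-like cells held Plcb1 (17.6-fold higher, 11.1 to 29.6) and Adamdec1 (8.80-fold higher, 5.17 to 16.1), with Cdk8 (5.32-fold lower, 4.73 to 5.998) and Cmss1 (4.68-fold lower, 4.47 to 4.91) lowest.

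Against CDK8i alone, CDK8i plus aCTLA4 had T-like cells at 8.64% against 4.79% of leukocytes, a log2 ratio of 0.85 (0.49 to 1.21). B-like cells were at 15.5% against 8.94%, a log2 ratio of 0.79 (0.54 to 1.05). Interferon gamma genes in epithelial-like cells had 3 of 3 measured members higher and 0 lower (median log2 fold 2.86, counting interval 1.72 to 3.89, 2.51 relative to all genes, 2.76 without the duct-gene cluster, percentile 99.2 of random lists), with the all-gene shift at 0.35 and 15 of 80 against 1 of 141 cells in the duct-gene cluster. The measured members were Stat1 (7.44-fold higher, 1.54 to 70.7), Irf1 (7.25-fold higher, 3.92 to 14.4) and Cd274 (6.06-fold higher, 1.60 to 33.8). Of the 57 and 97 fibroblast-like cells, 57.9% and 1.03% lay in the cluster led by Clec3b and Gsn and 14.04% and 54.64% in that led by Cfd and Car3. In them inflammatory CAF genes had 16 of 17 measured members higher and 1 lower (median log2 fold 2.09, counting interval 1.91 to 2.28, percentile 100 of random lists). Ccl2 (1.85-fold lower, 1.35 to 2.56) and Cxcl1 (1.505-fold higher, 1.30 to 1.74) stood lowest in the list. Ccl11 (17.3-fold higher, 11.5 to 27.0) and Saa3 (13.1-fold higher, 9.80 to 17.8) stood highest. Myofibroblast genes had 0 of 14 measured members higher and 13 lower (median log2 fold -1.77, counting interval -2.14 to -1.63, percentile 0 of random lists). Tnc (9.21-fold lower, 6.69 to 13) and Cthrc1 (6.74-fold lower, 4.11 to 11.8) stood lowest in the list. Fap (1.37-fold higher, 0.989 to 1.89) and Col8a1 (2.63-fold lower, 2.16 to 3.24) stood highest. Type I interferon genes of macrophage or monocyte-like cells, 32.7% against 56.5% of them in 1 cluster, had 16 of 19 measured members higher and 0 lower (median log2 fold 1.05, counting interval 0.93 to 1.26, percentile 100 of random lists). Oas1a (1.16-fold lower, 0.933 to 1.44) and Bst2 (1.47-fold higher, 1.36 to 1.59) stood lowest in the list. Ifit1bl1 (at least 5.79-fold higher) and Ifit3b (3.69-fold higher, 1.20 to 15.1) stood highest. Epithelial-like single genes were Clca1 (at least 68.3-fold higher), carried by at most 4 cells, Rora (264-fold higher, 46.8 to 10507) and Dcdc2a (156-fold higher, 42.6 to 1299), and lower Tff2 (33.7-fold lower, 13 to 125), Birc5 (52.6-fold lower, 9.20 to 2103) and Tff1 (10.1-fold lower, 8.17 to 12.7).

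Against aCTLA4 alone, CDK8i plus aCTLA4 had T-like cells at 8.64% against 5.27% of leukocytes, a log2 ratio of 0.71 (0.30 to 1.13). Neutrophil-like cells were at 23.2% against 32.6% (340 of 1043), a log2 ratio of -0.49 (-0.65 to -0.32). Interferon gamma genes in epithelial-like cells had 3 of 4 measured members higher and 1 lower (median log2 fold 1.42, counting interval 0.36 to 2.44, 1.02 relative to all genes, 1.30 without the duct-gene cluster, percentile 86.5 of random lists), with the all-gene shift at 0.40 and 15 of 80 against 1 of 72 cells in the duct-gene cluster. Gbp7 (1.83-fold lower, 0.509 to 8.11) and Cd274 (1.94-fold higher, 0.686 to 5.89) stood lowest in the list. Irf1 (6.39-fold higher, 3.32 to 13.5) and Stat1 (3.70-fold higher, 0.923 to 21.2) stood highest. T-like proliferation genes had 18 of 22 measured members higher and 1 lower (median log2 fold 1.38, counting interval 0.89 to 1.57, 1.27 relative to all genes, percentile 100 of random lists), with an all-gene shift of 0.10 in this class. E2f1 (1.82-fold lower, 0.402 to 6.80) and Mcm4 (1.18-fold higher, 0.584 to 2.63) stood lowest in the list. Birc5 (15.1-fold higher, 2.60 to 607) and Ube2c (11.2-fold higher, 1.91 to 455) stood highest. Epithelial-like single genes were Clca1 (at least 51.0-fold higher), Tff3 (at least 44.0-fold higher) and Muc2 (at least 39.4-fold higher), again in at most 4 cells, and lower Retnlg (446-fold lower, 79.7 to 17653), Nppb (at least 36.5-fold lower) and Pmvk (18.1-fold lower, 12.0 to 28.5).

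**Figure D2:**
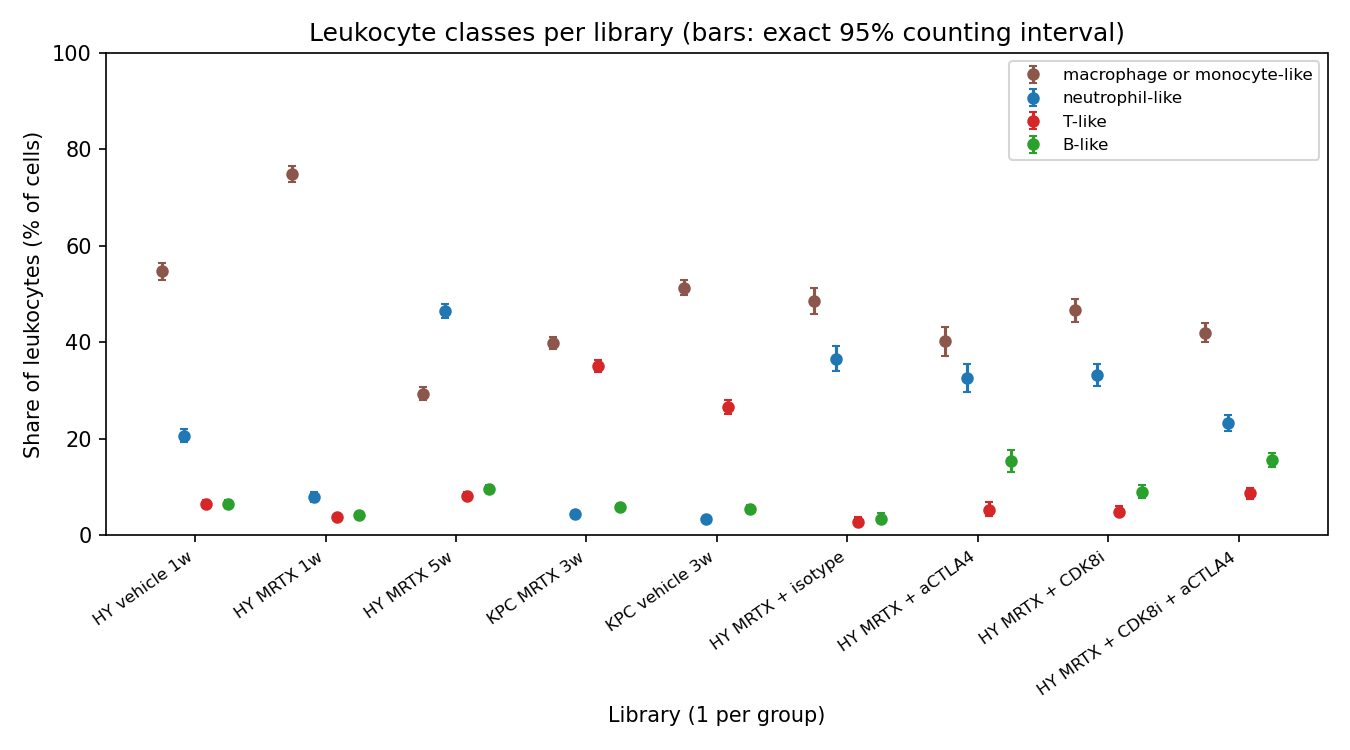
Share of leukocytes (vertical axis, % of cells) that were macrophage or monocyte-like, neutrophil-like, T-like or B-like in each of the 9 libraries (horizontal axis). Points are 1 library each and bars are exact 95% counting intervals. Neutrophil-like cells lie at 46.4% in the HY library with 5 weeks of MRTX1133 and at 7.85% in that with 1 week.

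Cdk8, the kinase in the title of the series (ENSMUSG00000029635, GRCm38 chromosome 5, 146231230 to 146302874), was compared by class. With 5 weeks of MRTX1133 against vehicle in HY tumours, it was 12.1-fold higher (11.8 to 12.5) in epithelial-like, 25.7-fold higher (24.0 to 27.5) in fibroblast-like and 7.49-fold higher (7.23 to 7.77) in macrophage or monocyte-like cells. In these classes it was also higher at 1 week, at 839 against 136, 778 against 87.2 and 518 against 123 CPM. The ribosomal RNA-like gene Gm42418 was also higher at 5 weeks, at 59129 against 1814 CPM in epithelial-like cells.

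In KPC689R tumours Cdk8 with MRTX1133 against vehicle was 1.04-fold lower (1.005 to 1.08) in epithelial-like, 1.13-fold higher (1.08 to 1.18) in macrophage or monocyte-like and 1.11-fold higher (1.04 to 1.18) in T-like cells.

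With CDK8i against isotype, Cdk8 was 2.40-fold lower (2.18 to 2.65) in epithelial-like, 2.44-fold lower (2.32 to 2.56) in macrophage or monocyte-like and 4.03-fold lower (3.62 to 4.50) in neutrophil-like cells. Gm42418 was lower with it, at 34137 against 60722 CPM in epithelial-like, 20218 against 39563 CPM in macrophage or monocyte-like and 10775 against 26107 CPM in neutrophil-like cells. Cdk8 was also lower than isotype with aCTLA4, at 960.4 against 1634 CPM in epithelial-like and 328 against 638 CPM in neutrophil-like cells.

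**Figure D3:**
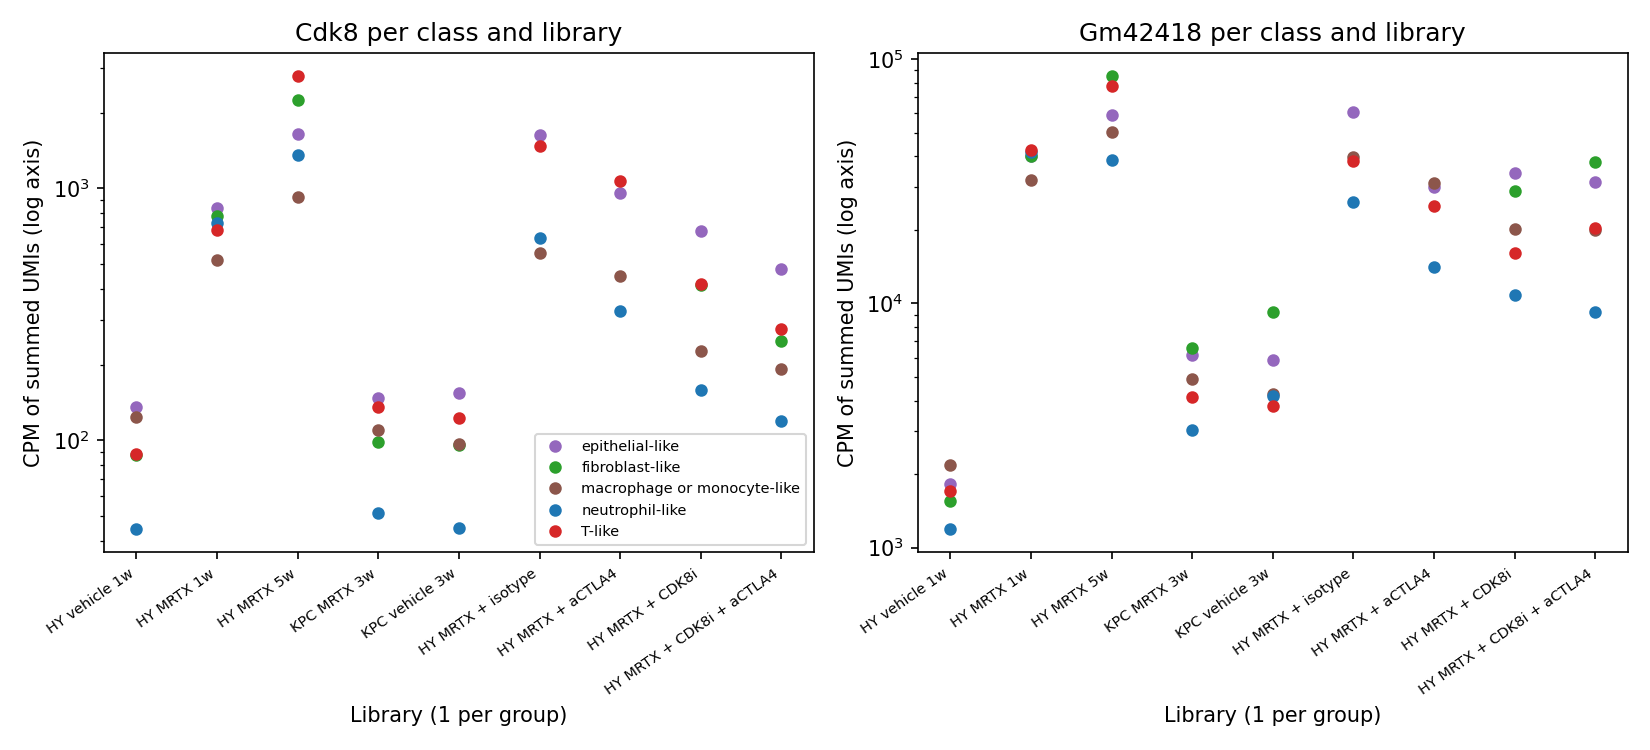
CPM of summed UMIs (vertical axes, log scale) of Cdk8 on the left and of the ribosomal RNA-like gene Gm42418 on the right, per library (horizontal axes) and cell class (colours), for classes with at least 30 cells. In epithelial-like cells Cdk8 lies at 136 CPM in the HY vehicle library and both genes are lower there and in the KPC689R libraries than in the other HY libraries.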

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

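These results came from a comparison of both models chosen after the list medians were seen, and no test of the difference was run. In each, both HY comparisons of MRTX1133 with vehicle (1 week and 5 weeks) lay beyond counting error on one side of the all-gene median and the KPC689R comparison (3 weeks) on the other. The models also differ in duration, and the HY comparisons share the vehicle library. The classes also hold different clusters in the libraries compared. Values are median log2 folds relative to all genes, given as KPC689R, then HY at 1 week and at 5 weeks.

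MHC class I genes in epithelial-like cells had -0.53 against 1.82 and 1.32. The 1-week median before the shift was 1.96, and 1.06 without the duct-gene cluster, which held 122 of the 160 cells. In neutrophil-like cells, chemokine and cytokine genes had -0.42 against 1.52 and 0.42, neutrophil activation genes -0.51 against 1.64 and 0.32, and dissociation stress genes -0.49 against 0.88 and 0.58. The KPC689R class here leaves out an unnamed cluster with neutrophil genes, larger with vehicle than the class itself. With it counted in, the values were -0.63 against 1.49 and 0.42, -0.54 against 1.49 and 0.18, and -0.73 against 0.50 and 0.20. Dissociation stress genes had -0.25 against 1.22 and 0.34 in fibroblast-like cells, and -0.0729 against 1.07 and 0.41 in macrophage or monocyte-like cells. Inflammatory CAF genes in fibroblast-like cells had 0.32 against -0.12 and -1.20. Proliferation genes had 0.81 against -3.72 and -2.61 in fibroblast-like cells, and 0.17 against -0.97 and -2.72 in T-like cells. Tumour-associated macrophage genes had 0.19 against -0.80 and -0.45 in macrophage or monocyte-like cells.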

How the results depend on the processing

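Removal of the duct-gene cluster, adding the unnamed tumour-gene cluster and counting the unnamed neutrophil-gene cluster, in shares and in neutrophil-like lists, were chosen after seeing the data. No paired analysis was possible, as groups share only replicate 1. Cell number limited the 4 libraries with an added treatment, where the epithelial-like class held 68 to 141 cells. Epithelial-like interferon gamma medians with both agents had no value with a minimum of 50 UMIs or after thinning. Free RNA subtraction was not run for the KPC689R and added-treatment libraries, and for 5 weeks only the other library was corrected. The free share set for HY vehicle, 9.89% of a library with 0.604% acinar enzyme UMIs, exceeds the 0.024% its epithelial-like class held. Acinar folds against it therefore rest on the floor. The cause was not tested for other values.

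The ERK output medians moved with thinning to -0.88 (HY 1 week against vehicle), -2.18 (5 weeks against vehicle), -1.45 (5 weeks against 1 week) and -0.19 (KPC689R). Median-ratio scaling gave -1.06 (5 weeks against vehicle) and -0.0614 (KPC689R), and turned 5 weeks against 1 week to 0.0900. Without the duct-gene cluster that median was -0.0934. The log2 ratio of T-like shares at 5 weeks against vehicle was 0.64 without doublet removal. As a share of all cells it was 0.81 there, 1.66 for 5 weeks against 1 week and 0.28 for KPC689R, and 0.54 for KPC689R with the neutrophil-gene cluster counted. The KPC689R neutrophil-like ratio turned to -0.78 by marker score and -1.12 with that cluster counted.

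Median-ratio scaling also turned some values. At 1 week against vehicle in macrophage or monocyte-like cells, type I interferon was 0.0851 and interferon gamma 0.17. At 5 weeks against vehicle in epithelial-like cells, proliferation was 0.45, normal duct and lineage 0.0540, p53 targets 0.41, dissociation stress 0.14 and Kras 0.55, with myofibroblast CAF in fibroblast-like cells at 0.0013 and the Mediator kinase module in macrophage or monocyte-like cells at 0.13. Epithelial-like proliferation with CDK8i against isotype was -0.0079. With both agents against isotype, neutrophil-like dissociation stress was -0.0724 and Kras -0.0336, and epithelial-like Kras -0.17. Without the duct-gene cluster the Mediator kinase module at 1 week was -0.08046.

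Free RNA subtraction turned values at 5 weeks. Against vehicle, epithelial-like acinar enzymes were 4.91, MHC class II 6.41 and type I interferon 0.0397, and fibroblast-like MHC class II was 5.39 and antigen-presenting CAF 3.73. Against 1 week, epithelial-like chemokines and cytokines were 0.16, MHC class II 1.52 and Cxcl2 4.47, and fibroblast-like MHC class II was 2.89, antigen-presenting CAF 1.55 and Cxcl2 0.79. Of other list medians, 290 stayed within their counting interval and 128 moved under scaling. Of named gene folds, 366 stayed within and 1 moved with the 1000 UMI minimum, and 275 stayed within and 89 moved under scaling. Free RNA subtraction left 116 other list medians within and moved 40, and left 99 named gene folds within and moved 37. With the neutrophil-gene cluster counted, 28 neutrophil-like list medians stayed within and 17 moved. Without the duct-gene cluster 98 list medians stayed within and 40 moved. Classing by marker score left 74 class shares within and moved 79, and unthinned cells left 3 T cell subset shares within and moved 24.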

Other observations

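Tests of tumour cell response for Cdk8, free RNA in T-like cells and gene length with both agents were chosen after the result was seen. Uba52 values were picked out after they were seen. Uba52, which encodes a ubiquitin fusion protein, differed between libraries in tumour and immune classes. Epithelial-like cells had 1183 CPM with CDK8i, 832 CPM in KPC689R vehicle, 605 CPM with aCTLA4, and 116 CPM with both agents. Macrophage or monocyte-like Uba52 was 419 CPM, 480 CPM, 196 CPM and 48.6 CPM in the same libraries.

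Cdk8 was higher in each of 6 classes of the HY library with 5 weeks of MRTX1133 than with vehicle. The smaller of the T-like and neutrophil-like folds was 2.52 times the epithelial-like fold. With free RNA open, this cannot rule out a tumour cell response alone. Reads shared with ribosomal RNA-like genes stay open: the SD of log2 Cdk8 over Gm42418 was 0.498 of the SD of log2 Cdk8 over 53 class and library sums, just under the bound of 0.5 set before. It ran from 0.399 without HY vehicle to 0.606 without HY MRTX1133 5w, and the requirement that this range clear the bound was added after the value was seen, so this test cannot tell. For other genes the share was 0.440 for Cmss1, 0.453 for Lars2, 0.629 for Camk1d, 0.855 for AY036118, 1.08 for Gm26917, 1.22 for Cdk19 and 1.22 for Ccnc. Free RNA stays open in macrophage or monocyte-like cells, with a slope of Cdk8 UMIs on depth of 0.310 (0.263 to 0.356), between the bounds of 0.25 and 0.75 set before. It also stays open in epithelial-like (0.353) and neutrophil-like cells (0.563). The T-like slope of 0.911 (0.789 to 1.045) lay above the upper bound, beside 0.919 for Cmss1 and 0.835 for Gm42418 in the same cells. Where depth differs through capture, free RNA would rise with depth too, so the T-like slope does not exclude it.

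ERK output genes were lower in epithelial-like cells of the HY MRTX1133 libraries than of vehicle. Among lists matched on expression and gene body length the 5-week median of -1.79 lay at percentile 0, with matched lists between -0.86 and 0.22, which argues against gene length or loss of nuclear RNA as the whole cause. Without the duct-gene cluster the 1-week median was -1.49 (-1.78 to -1.13) in 38 cells, which argues against duct-gene cells as its source. Lower ERK signalling under the inhibitor was not tested, since no protein or phosphorylation was measured. The time difference at 5 weeks and differences between pooled mice were not tested.

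ERK output genes were higher in epithelial-like cells with CDK8i plus aCTLA4 than with isotype. Without duct-gene and goblet-gene cells the median was 1.35 (0.85 to 1.70) in 62 and 64 cells. The 18 members outside the dissociation stress list, of 19 measured, had 1.33 (0.92 to 1.68). Leaving out so few members could hardly move the median, and stress genes as a list were at 2.16, so dissociation stress stays open. The median of the full list lay at percentile 99.97 of lists matched on expression and gene body length. The values argue against duct or goblet cells and against gene length as the whole cause. A difference between the pooled mice, in their number of tumour cells or sex, may also underlie it and was not tested.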
